A study of Dinoroseobacter shibae DFL 12 = DSM 16493 with 24 samples.

How the data were processed

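Cultures of Dinoroseobacter shibae were grown with oxygen in saltwater minimal medium with 16.9 mM succinate to an optical density of 0.5, moved to closed serum flasks with 25 mM pyruvate at 30 °C in the dark, used up the oxygen within 30 min and then received 50 nM NO, per the labels' protocols. Total RNA sampled directly before NO and 30 min after it was labelled with Cy3 and hybridised to Agilent arrays of 1 colour, per the labels. The 24 arrays fell into 8 groups of 3 by strain and stage, and the replicate numbers come from the sample titles.

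The spot intensity in the deposited scanner files was extracted with Agilent Feature Extraction 10.7.3.1, with spatial and multiplicative detrending, per the file headers. The processed signal used here is an intensity that this software had background-subtracted and detrended, with dim spots set to a surrogate floor, per the file headers. Its 75th percentile differed between arrays, so it was scaled here. The authors also deposited a matrix of log2 values of the same arrays, for which the submitters' processing notes name limma without a version. Its columns correlated with the log2 mean signal of the same array at 0.985 to 0.999. The column medians were 9.72 in wt before NO, 9.72 after it, 10.2 and 10.3 in ΔfnrL, 9.98 and 10.1 in ΔdnrD and 9.8 and 9.86 in ΔdnrF, alike for the 3 arrays of a group, whose quantiles were nearly equal, as after quantile normalization within each group. How that scale was set and whether values were centred stays unknown, so the matrix served only as an alternative.

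Each array held 14999 spots, of which 687 were controls. The other 14312 carried 12476 probes, 12272 printed once and 204 printed 10 times, for 4102 genes, 4007 of them with 3 probes. Of the gene identifiers 3980 matched a locus tag of the reference gene table of assembly ASM1814v1, 122 did not, and 1530 have a symbol from the array files or that table. Symbols and product names in the array files disagree in the plasmid transfer region of pDSHI03, so its genes are given by locus tag, and Dshi_0591 is named by its product. Coordinates are not given, since the build of the array design is not given in the sources used here, and no genome was used here. Control spots and spots marked as outliers (44 to 185 per array) were left out, and 0 spots were saturated. The 75th percentile of the processed signal was 3.07 to 6.83 times the median signal of the negative controls on the same array. Between arrays Pearson r across genes ran from 0.967 to 0.996 within groups and from 0.767 to 0.989 between groups.

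Levels are log2 of the processed signal minus the array's 75th percentile of it, averaged over the spots of a probe and then over the probes of a gene. A gene was tested if at least 1 probe was well above background, by the file's own mark, on at least 3 of the 24 arrays, which left 3721. A single model with a mean per group and 16 residual degrees of freedom was fitted to all arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values in the text come from limma. The comparisons were after minus before NO in each strain, mutant minus wt at each stage, and the difference of the NO responses, mutant minus wt. Probes of a gene did not always move alike, and all probes of a called gene had the same sign in 88.7% to 100% of calls. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 35 lists of a comparison, for lists with at least 3 measured members, and again with an estimated correlation. Files were read with the R packages data.table (version 1.17.8) and jsonlite 2.0.0, and pandas 2.3.3 and matplotlib 3.10.9 in Python 3.11.15 served for annotation and plots.

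The comparisons, lists, rule for naming genes and alternatives other than those named as added were fixed before the data were examined. The rule took the 10 largest rises and falls among called genes with non-overlapping groups for the NO responses and for the mutants before NO, and the 5 largest for the other comparisons. It added the deleted genes and dnrE, up to 4 called members of each list described and the denitrification genes. Genes without a symbol carry their locus tag, with the annotated product where it says more than hypothetical protein. Alternatives were normexp background (offset 50) on the mean and local background signals, quantile normalization, median scaling, the authors' matrix values, array weights, the brightest probe of a gene, no filter, only probes well above background, only the arrays compared, the replicate number or slide as a block, a threshold of 1 on the absolute log2 difference, and each array left out. Relative to the median of all genes, which the 75th percentile scaling left at 0.12 for ΔfnrL and 0.12 for ΔdnrF against wt before NO and at 0.16 for ΔdnrF after it, other scalings shift all values. Quantile normalization put the median at -0.16 and -0.11 for ΔdnrD and ΔdnrF before NO and at -0.18 and -0.12 after it. Median scaling put it at -0.11 and -0.18 for ΔdnrD before and after NO and -0.10 for its difference of responses. The authors' matrix put it at 0.44 and 0.61 for ΔfnrL and 0.25 and 0.34 for ΔdnrD against wt before and after NO, and at 0.13 and 0.11 for the NO responses of ΔfnrL and ΔdnrD.

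Each of the 3 slides held 8 arrays, 1 per group, and slide, scan and replicate number coincide, though their blocks differ for NO responses. Strain set column and stage row on every slide, confounding place with both. Deviations from group means before and after NO correlated in 12 pairs of the same strain and number (median r 0.41, 0.0225 to 0.78). The median was -0.181 for other numbers and 0.149 for the same number in other strains. All pairs but 1 of ΔdnrD were over 0.1. The slide may add to this. The main fit used no pairs. The method was tested on simulated data for the 3721 genes of the NO comparison in wt. It recovered 30 of 67 genes changed by 0.5 on the log2 scale, 66 of 67 by 1 and 66 of 66 by 2, 0 in the wrong direction. Of 170 calls 8 were false (4.71%), and of 20 lists of 30 genes only the 1 shifted by 0.5 was called. Gene correlation was not simulated.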

Results

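Transcript levels of Dinoroseobacter shibae, a marine bacterium that respires oxygen and can grow by denitrification, were measured on 24 Agilent arrays of 1 colour. The wild type (wt) and strains lacking the regulator gene fnrL (ΔfnrL), dnrD (ΔdnrD) or dnrF (ΔdnrF) were each sampled directly before and 30 min after the addition of 50 nM nitric oxide (NO). The cultures had used up their oxygen in closed flasks in the dark. FnrL, DnrD and DnrF belong to the Crp/Fnr family of regulators. The design asked which genes each strain induced or repressed under NO, with the sample before NO as the reference. Each of the 8 groups held 3 arrays of biological replicates. The 75th percentile of the processed signal ran from 416 to 3377 between arrays. Between 61.7% and 79% of spots were well above background. That share was 76.4% ± 2.09 (SD, n = 3) in wt before NO and 70.6% ± 2.77 after it. In ΔfnrL it was 75.9% ± 1.61 and 69.3% ± 2.04, in ΔdnrD 70.9% ± 5.43 and 70.7% ± 2.04 and in ΔdnrF 76% ± 2.82 and 66.6% ± 4.29. Values beside gene names are log2 differences ± SE of the fit, from 3 arrays against 3. Where a gene was well above background on only some arrays of a group, or in a difference of responses on none, their number follows. Such a difference of responses is only a fitted value. A gene not well above background on any array of the dimmer group is given as at least N-fold. This bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the gene's own signal and the lowest signal well above background. A gene counts as above background by 1 probe or more, so its mean can lie under that lowest signal. Where raising such arrays to it moves the value by over 0.5, the value then follows as floor. No fold is given where that bound is under 1 or both groups are below background. Each gene list is given with its members up and down and the median log2 difference. Where members lay below background, the median with these at their bounds (0 where there is none) follows if it differs, then the medians on slides 1, 2 and 3. For a difference of responses each response is set to its bound, which makes the difference itself no bound, and the number of such members is added. Where leaving out 1 array ended a call of a gene or list, its stage and replicate number and the highest adjusted p follow. The adjusted p of limma's camera test is given with the preset and then with an estimated correlation between genes.

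The deleted genes were compared first, as a check of the labels. On the log2 scale relative to each array's 75th percentile, fnrL stood at -0.93 ± 0.13 (SD, n = 3) in wt before NO. It was not well above background on any of the 6 ΔfnrL arrays, at least 6.01-fold lower before NO (adjusted p = 1.18e-15). The dnrD transcript stood at 1.37 ± 0.07 in wt before NO and was not well above background in ΔdnrD, at least 22.4-fold lower (adjusted p = 7.01e-20). The dnrF transcript stood at 3.25 ± 0.07 in wt and was below it in ΔdnrF, at least 99.7-fold lower (adjusted p = 1.36e-20). The deleted gene of the labelled strain was well above background on 0 of its arrays, and another strain's deleted gene was missing on 0 of the 24 arrays. Among the regulators, dnrF was lower in ΔfnrL than in wt (log2 difference -5.05 ± 0.18 before NO, adjusted p = 6.06e-16), and dnrD was higher there by 0.72 ± 0.15 (adjusted p = 0.000852).

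**Figure D1:**
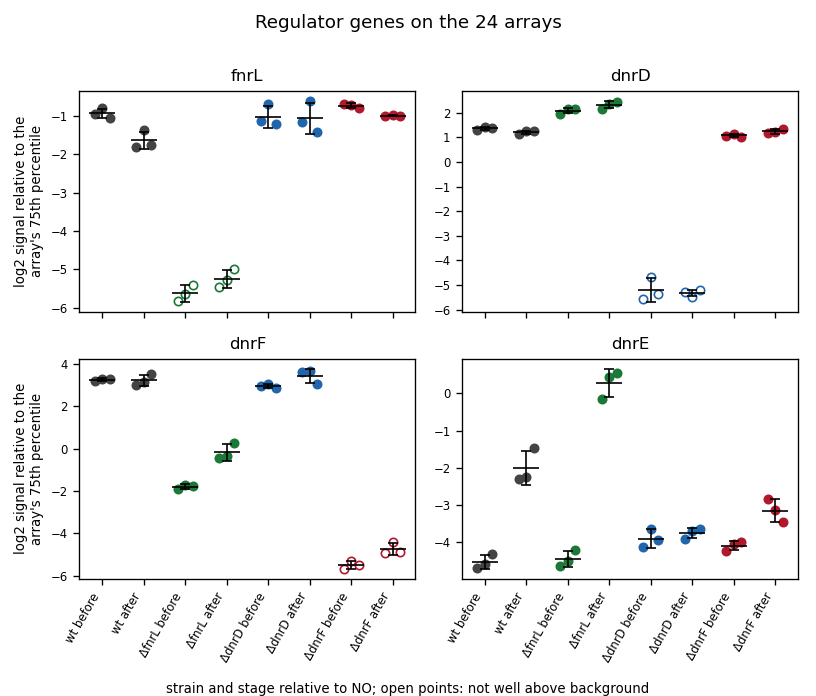
Signal of the regulator genes fnrL, dnrD, dnrF and dnrE as log2 relative to the array's 75th percentile, with 1 point per array, open where not well above background, and the mean ± SD of each group of 3 arrays. Each deleted gene was below background on the 6 arrays of its own mutant. After NO dnrE rose from -4.52 ± 0.19 to -2.01 ± 0.46 in wt and from -4.44 ± 0.22 to 0.29 ± 0.37 in ΔfnrL.

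In wt, the largest rises after NO were those of norC (2.99 ± 0.28, floor 2.14), dnrE (2.52 ± 0.21, floor 1.67), nirG (2.27 ± 0.32, 1 of 3 before, floor 1.35) and nirH (1.87 ± 0.37, 2 of 3 before). Others were those of apbE Dshi_3168 (1.81 ± 0.24), norB (at least 1.45-fold) and hemA Dshi_3190 (1.22 ± 0.27). The norC and norB genes encode NO reductase, and the nirG and nirH genes, annotated as AsnC family regulators, belong to heme d1 synthesis for nitrite reductase. The hemA gene encodes the first enzyme of heme synthesis, and dnrE encodes another Crp/Fnr regulator. Hypothetical proteins among the 10 largest rises were Dshi_3192 (1.15 ± 0.16), Dshi_0495 (1.11 ± 0.26, floor 0.58) and Dshi_0416 (0.93 ± 0.15, 2 of 3 before). Of the other denitrification genes, nirS, the nitrite reductase, stood at 0.80 ± 0.30 (adjusted p = 0.0922), short of the threshold, but passed with the replicate block (adjusted p = 0.00338), median scaling, the brightest probe or the authors' matrix values. Nor did nosZ, the nitrous oxide reductase, pass (-0.32 ± 0.52, adjusted p = 0.736). The nosR gene RDRS03175 rose by 0.70 ± 0.17 and napF fell by 0.54 ± 0.12. The fnrL transcript itself fell by 0.71 ± 0.18 (adjusted p = 0.0166). The largest falls were those of the L-PSP endoribonuclease gene Dshi_3461 (-2.01 ± 0.22, 2 of 3 after, floor -1.17), the DUF411 protein gene RDRS03757 (-1.73 ± 0.18) and the integrase gene Dshi_3696 (-1.03 ± 0.19, floor -0.12). Hypothetical protein genes among the falls were Dshi_3765 (-1.66 ± 0.17), Dshi_3879 (-1.37 ± 0.20, 2 of 3 after, floor -0.04), Dshi_1865 (-1.14 ± 0.22, 1 of 3 after, floor 0.09), Dshi_0047 (-1.08 ± 0.21, 1 of 3 after, floor -0.26) and Dshi_4137 (-1.04 ± 0.21, 2 of 3 after). The glutamate symporter gene gltS and the transport protein gene Dshi_1598 also fell (adjusted p = 0.00332 and 0.000912). No fold is given, since neither was well above background after NO. For the 20 genes, adjusted p ran from 2.96e-07 to 0.0127. By list, NO reductase genes had 2 of 3 up and 0 down (3 and 0 adjusted over the list alone). The median was 1.59 or 0.53 at the bounds (1.19, 1.43 and 2.14 by slide), with adjusted p = 0.000147 and 0.155. Nitrite reductase and heme d1 genes had 2 of 8 up and 0 down (3 and 0 adjusted over the list alone). The median was 0.46 (0.42, 0.44 and 0.50 by slide), with adjusted p = 0.0039 and 0.891. Without 1 array the call ended for Dshi_0495 (before 1, after 2, p up to 0.0634), fnrL (any but before 3, after 2, p up to 0.0687) and nosR RDRS03175 (before 1, p up to 0.0513).

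The count in wt was 364 of 3721 genes, 132 higher and 232 lower after NO. Of these, 19 changed by at least 1 on the log2 scale, 364 moved the same way on all 3 slides and 19 lay below background in both groups. The count became 0 with normexp background (114 by limma at an unadjusted p under 0.05), 234 on the authors' matrix values, 92 with only the arrays compared and 947 with the replicate block. Without wt replicates 1 and 2 before NO it was 88 and 182. The split became 322 higher and 197 lower with median scaling.

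In ΔfnrL, single denitrification and heme genes rose after NO. Transcripts below background before NO and measured after it were nirH (at least 27.5-fold), Dshi_1454 (at least 20.5-fold), norC (at least 22.1-fold) and Dshi_3192 (at least 9.08-fold). Others were nirS (at least 7.58-fold), nirG (at least 4.77-fold) and Dshi_0814 (at least 4.45-fold). Genes above background on both sides rose by large amounts too, with apbE Dshi_3168 (5.38 ± 0.24, floor 4.74), dnrE (4.73 ± 0.21, floor 3.80) and hemA Dshi_3190 (4.64 ± 0.27). The norB gene rose at least 3.03-fold, dnrF by 1.62 ± 0.18 and the heme d1 gene nirJ by 1.99 ± 0.20. Both nosR genes rose, Dshi_3193, next to nosZ, by 1.73 ± 0.20, floor 1.05 and RDRS03175 by 1.81 ± 0.17, but nosZ stood at 0.50 ± 0.52 (adjusted p = 0.576). The largest falls were those of RDRS03757 (-1.98 ± 0.18), rpmG (-1.71 ± 0.44), pqqA (-1.38 ± 0.16), infA (-1.30 ± 0.24) and the putative methylase gene RDRS01914 (-1.16 ± 0.18), and of the hypothetical protein genes Dshi_3765 (-1.71 ± 0.17) and Dshi_3654 (-1.17 ± 0.16). Here rpmG encodes a ribosomal protein, infA a translation initiation factor and pqqA the precursor of the cofactor PQQ. The endoribonuclease gene Dshi_3461 fell at least 1.54-fold, and Dshi_4067 and Dshi_0047 fell with no fold given (adjusted p = 0.000159 and 0.000534). Over the set of 20 genes, adjusted p ran from 4.94e-16 to 0.0119.

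By list, nitrite reductase and heme d1 genes had 5 of 8 up and 0 down (7 and 0 adjusted over the list alone). The median was 1.73 or 1.0 at the bounds (1.21, 2.16 and 1.82 by slide), with adjusted p = 5.96e-12 and 0.0748. The nor genes had 2 of 3 up and 0 down (3 and 0 adjusted over the list alone). The median was 3.57 or 1.60 at the bounds (2.93, 3.96 and 3.82 by slide), with adjusted p = 3.12e-07 and 0.0272. The heme and tetrapyrrole list had 5 of 17 up and 1 down (5 and 1 adjusted over the list alone). The median was -0.01 with a mean of 0.62 and a test pointing up (0.00, -0.03 and 0.02 by slide), turning to 0.04 with median scaling and 0.08 with normexp background, with adjusted p = 0.0144 and 0.0943 (0.172 with the replicate block). Members that rose included bchE (3.19 ± 0.14), hemP (1.91 ± 0.22) and hemN Dshi_0659 (1.31 ± 0.16, floor 0.47).

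The count in ΔfnrL was 522 of 3721 genes, 195 higher and 327 lower. Of these, 57 changed by at least 1 on the log2 scale, 522 moved the same way on all 3 slides and 28 lay below background in both groups. The count became 79 with normexp background, 2246 on the authors' matrix values, 876 with array weights and 1051 with the replicate block. Without ΔfnrL replicate 2 before NO it was 282. The split became 293 higher and 293 lower with median scaling and 1630 higher and 616 lower with the authors' matrix values. The sign turned for Dshi_0047, Dshi_3654 and Dshi_4067 with the authors' matrix values and normexp background and for Dshi_3461 with normexp background.

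**Figure D2:**
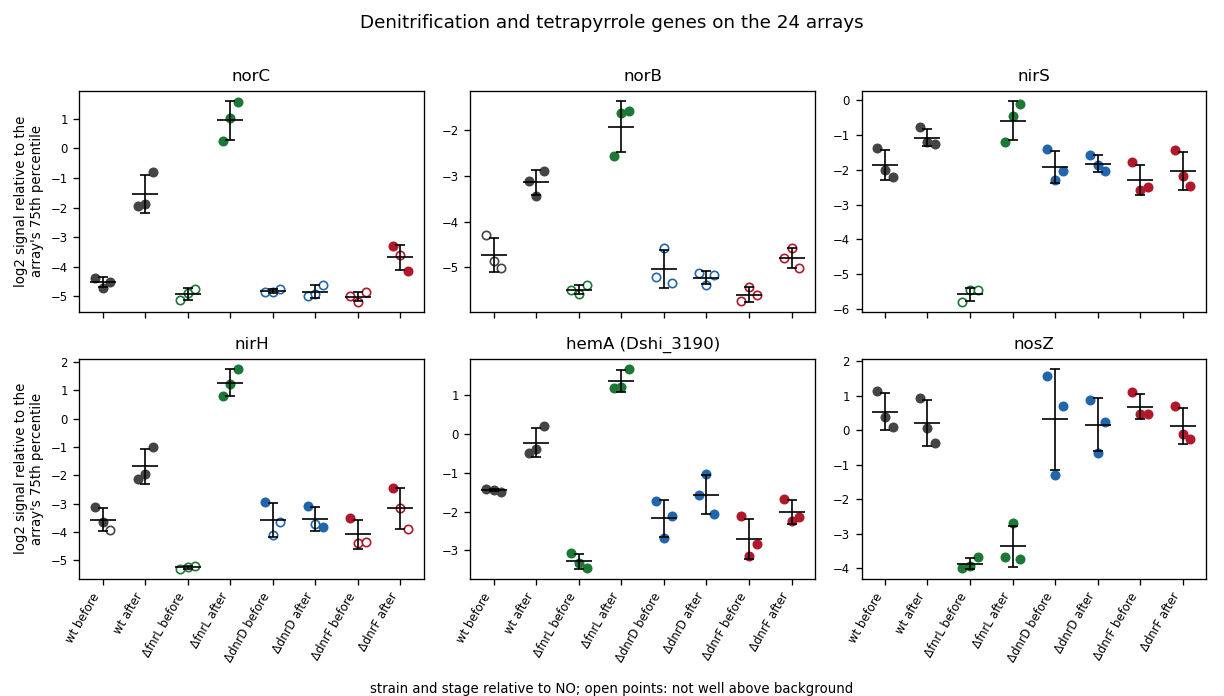
Signal of norC, norB, nirS, nirH, hemA Dshi_3190 and nosZ as log2 relative to the array's 75th percentile, with 1 point per array, open where not well above background, and the mean ± SD of each group of 3 arrays. After NO, norC stood at -1.54 ± 0.65 in wt, 0.95 ± 0.65 in ΔfnrL, -4.85 ± 0.21 in ΔdnrD and -3.69 ± 0.42 in ΔdnrF.

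In ΔdnrD the NO reductase and heme d1 genes did not pass after NO. The norC and norB transcripts were below background in both groups (adjusted p = 0.965 and 0.6). Short of the threshold too were nirS (0.08 ± 0.30, adjusted p = 0.873), nirH (0.03 ± 0.37, 2 of 3 after, 1 of 3 before, adjusted p = 0.965), dnrE (0.15 ± 0.21, adjusted p = 0.654) and nosZ (-0.16 ± 0.52, adjusted p = 0.857). The largest rises were those of Dshi_3769 (2.18 ± 0.42, 2 of 3 before, floor 1.04), dcuC (at least 1.43-fold, 2 of 3 after), Dshi_3929 (1.54 ± 0.15), the transposase gene Dshi_0934 (1.39 ± 0.22) and Dshi_3760 (1.34 ± 0.25, floor 0.84). Others were those of Dshi_1454 (1.25 ± 0.34), the UspA domain protein gene Dshi_2686 (1.23 ± 0.17), the integrase gene Dshi_3751 (1.23 ± 0.23) and the metal-transporting ATPase gene Dshi_3789 (1.22 ± 0.39). The dcuC gene encodes a C4-dicarboxylate carrier. Dshi_4181 rose too, with no fold given since it was below background before NO (adjusted p = 0.0178). The largest falls were those of Dshi_4067 (-1.38 ± 0.20), cysG (-1.33 ± 0.44), the citrate lyase gene Dshi_2874 (-1.10 ± 0.26), the regulator gene Dshi_0407 (-1.08 ± 0.22) and rplM (-1.06 ± 0.13). Others were those of Dshi_2991 (-1.03 ± 0.18, 1 of 3 after, floor -0.03), atpH (-1.02 ± 0.12), Dshi_0919 (-1.0 ± 0.20) and repB Dshi_3744 (-1.0 ± 0.15). Dshi_3461 fell at least 1.11-fold. Over the 20 genes, adjusted p ran from 4.23e-06 to 0.0343. By list, periplasmic nitrate reductase genes had 0 of 7 up and 5 down (0 and 6 adjusted over the list alone). The median was -0.47 (-0.34, -0.82 and -0.22 by slide), with adjusted p = 0.0222 and 0.935, lost without 1 array (before 1, after 2, p up to 0.108). Members that fell included napG (-0.69 ± 0.16), napB (-0.59 ± 0.19) and napH (-0.53 ± 0.17). Ribosomal protein genes had 0 of 54 up and 19 down (0 and 25 adjusted over the list alone). The median was -0.31 (-0.20, -0.65 and -0.13 by slide), with adjusted p = 8.71e-05 and 0.935, and rplJ fell by 0.99 ± 0.21. The call ended on leaving out 1 array for cysG (before 1 and 2, after 2, p up to 0.209), Dshi_1454 (after 2, p up to 0.0913), napB (before 1, after 2, p up to 0.235), napH (before 1 and 2, after 2, p up to 0.244), Dshi_3789 (any but before 1, after 3, p up to 0.107) and Dshi_4181 (before 1, after 1, p up to 0.107).

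The count in ΔdnrD was 785 of 3721 genes, 283 higher and 502 lower. Of these, 37 changed by at least 1 on the log2 scale, 771 moved the same way on all 3 slides and 7 lay below background in both groups. The count became 1 with normexp background, 1410 with array weights and 43 with only the arrays compared. Without ΔdnrD replicate 2 after NO it was 458. The split became 378 higher and 435 lower with median scaling and 944 higher and 188 lower with the authors' matrix values. The sign turned for Dshi_2874 and Dshi_2991 with normexp background and for repB Dshi_3744 with the brightest probe.

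In ΔdnrF norC passed (adjusted p = 0.00319), well above background on 2 of 3 arrays after NO and 0 before. Its mean after NO (-3.69) lay under each array's lowest such signal. The norB gene passed with both groups below background (adjusted p = 0.0214). In addition nirG rose (no fold given, adjusted p = 0.0435) and dnrE rose by 0.95 ± 0.21 (adjusted p = 0.00428). Short of the threshold were nirS (0.25 ± 0.30, adjusted p = 0.611), nirH (0.91 ± 0.37, 1 of 3 after, 1 of 3 before, adjusted p = 0.0855, but passing with the replicate block at 0.0251, array weights, the brightest probe or without ΔdnrF replicate 3 after NO at 0.0356) and nosZ (-0.57 ± 0.52, adjusted p = 0.486). The largest rises were those of Dshi_3929 (1.76 ± 0.15), Dshi_3769 (1.65 ± 0.42, 2 of 3 before, floor 0.74), Dshi_2686 (1.57 ± 0.17) and Dshi_0738 (1.42 ± 0.13). Others were those of Dshi_4225 (1.41 ± 0.37), Dshi_4224 (1.34 ± 0.45) and the RND transporter gene Dshi_0251 (1.32 ± 0.13). Dshi_4181, dcuC and norC, also among the 10, have no fold given. The largest falls were those of Dshi_4067 (-1.55 ± 0.20), Dshi_3461 (-1.5 ± 0.22, 2 of 3 after, floor -0.58), RDRS01914 (-1.05 ± 0.18), nth (-1.02 ± 0.18) and virB9 Dshi_3646 (-1.01 ± 0.28). Others were those of rplM (-0.99 ± 0.13), rodA Dshi_0591 (-0.96 ± 0.15, 1 of 3 after, floor 0.15), Dshi_0878 (-0.94 ± 0.17) and RDRS03757 (-0.92 ± 0.18). The nth gene encodes a DNA repair endonuclease and virB9 a part of a type IV secretion system of plasmid transfer. Besides, ugpA Dshi_0548 fell with no fold given (adjusted p = 0.00272). For the 20 genes, adjusted p ran from 4.02e-07 to 0.0403. Single arrays decided the call of dcuC (after 3, p up to 0.0662), nirG (any but after 3, p up to 0.176), norB (any but before 2, after 3, p up to 0.0892), virB9 Dshi_3646 (before 1, after 3, p up to 0.0649), Dshi_4224 (any, p up to 0.174) and Dshi_4225 (after 3, p up to 0.062).

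The count in ΔdnrF was 696 of 3721 genes, 385 higher and 311 lower. Of these, 32 changed by at least 1 on the log2 scale, 696 moved the same way on all 3 slides and 35 lay below background in both groups. The count became 3 with normexp background, 1080 on the authors' matrix values and 1390 with array weights. The count was 1194 with only the arrays compared and 1256 with the replicate block. Without ΔdnrF replicate 1 before NO it was 447. Without ΔdnrF replicate 3 after NO it was 410. The split became 299 higher and 383 lower with quantile normalization and 745 higher and 335 lower with the authors' matrix values.

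Whether the NO response differed between a mutant and wt was tested as the difference of the responses. In ΔfnrL the largest differences were those of Dshi_1454 (6.27 ± 0.48, 0 of 3 ΔfnrL before), nirH (4.64 ± 0.52, 0 of 3 ΔfnrL before, 2 of 3 wt before) and nirS (4.18 ± 0.42, 0 of 3 ΔfnrL before). Others were Dshi_3192 (4.16 ± 0.23, 0 of 3 ΔfnrL before) and Dshi_0814 (4.03 ± 0.30, 0 of 3 ΔfnrL before). Responses larger than in wt were also those of norC (2.88 ± 0.40, 0 of 3 ΔfnrL before), norB (1.99 ± 0.33, 0 of 3 ΔfnrL before, 0 of 3 wt before) and nirG (2.24 ± 0.45, 0 of 3 ΔfnrL before, 1 of 3 wt before). The same held for dnrE (2.22 ± 0.30), nosR Dshi_3193 (1.35 ± 0.28, floor 0.68) and nosR RDRS03175 (1.11 ± 0.24). For nirJ the difference was 1.60 ± 0.28 and for dnrF 1.65 ± 0.26. Responses lower in ΔfnrL were those of ctrA (-1.23 ± 0.18, 0 of 6 wt) and the plasmid transfer genes Dshi_3983 (-1.05 ± 0.19, 0 of 6 wt) and Dshi_3980 (-1.0 ± 0.23, 0 of 6 wt). Others were virB3 Dshi_3640 (-0.94 ± 0.21, 0 of 6 wt) and virB8 Dshi_3645 (-0.91 ± 0.20). Over the 10 genes with the largest differences, adjusted p ran from 8.42e-11 to 0.0365. By list, nitrite reductase and heme d1 genes had 4 of 8 up and 0 down (4 and 0 adjusted over the list alone). The median was 1.27 or -0.05 at the bounds, 7 below background in a group (0.82, 1.72 and 1.05 by slide), with adjusted p = 5.62e-16 and 0.0165. The nor genes had 2 of 3 up and 0 down (2 and 0 adjusted over the list alone). The median was 1.99 or 1.06 at the bounds, 2 below background in a group (1.75, 2.54 and 1.68 by slide), with adjusted p = 5.14e-07 and 0.0156. Heme and tetrapyrrole genes had 4 of 17 up and 0 down (5 and 0 adjusted over the list alone). The median was 0.07 (0.05, 0.01 and 0.05 by slide), turning to -0.17 with the authors' matrix values, with adjusted p = 2.49e-06 and 0.00368. Members included hemA Dshi_3190 (3.42 ± 0.39) and bchE (3.22 ± 0.20). Crp/Fnr regulator genes other than the deleted fnrL had 2 of 10 up and 0 down (2 and 0 adjusted over the list alone), with a median of 0.10 and adjusted p = 0.000773 and 0.066. Without 1 array the call ended for fnrL (any but wt before 3, after 2, ΔfnrL before 3, after 1, p up to 0.129), virB3 Dshi_3640 (any but wt before 3, after 3, ΔfnrL after 1, p up to 0.107), virB8 Dshi_3645 (any but wt before 3, after 1 and 2, ΔfnrL before 2, after 1, p up to 0.0912), Dshi_3980 (any but wt after 2 and 3, ΔfnrL after 2, p up to 0.131) and nosR RDRS03175 (wt before 1, after 2, ΔfnrL before 1 and 2, p up to 0.0694). The test called 35 genes, fnrL itself among them, 28 higher and 7 lower, of which 29 by at least 1 on the log2 scale and 35 the same way on all 3 slides. The count became 14 with normexp background, 21 with the brightest probe, 1545 on the authors' matrix values and 55 with the replicate block. The sign turned for nirJ with the brightest probe and for virB3 Dshi_3640 and Dshi_3983 with the authors' matrix values and normexp background and for Dshi_3980 with the authors' matrix values, the brightest probe and normexp background.

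In ΔdnrD lower responses than in wt were those of norC (-3.02 ± 0.40, 0 of 6 ΔdnrD) and norB (-1.77 ± 0.33, 0 of 6 ΔdnrD, 0 of 3 wt before). Others were nirG (-2.68 ± 0.45, 0 of 3 ΔdnrD after, 1 of 3 ΔdnrD before, 1 of 3 wt before) and dnrE (-2.37 ± 0.30, floor -1.66). The difference did not pass for nirH (-1.84 ± 0.52, 2 of 3 ΔdnrD after, 1 of 3 ΔdnrD before, 2 of 3 wt before, adjusted p = 0.066) or nirS (-0.71 ± 0.42, adjusted p = 0.335), though it did with the replicate block (adjusted p = 0.0185 and 0.0486), whose numbers do not pair all ΔdnrD samples, and for nirH without ΔdnrD replicate 2 before or 3 after NO (adjusted p = 0.0466 and 0.0483). It was also lower for the transfer gene RDRS03978 (-1.39 ± 0.33, 0 of 6 wt). Higher responses were those of cytC (1.57 ± 0.26), Dshi_3879 (1.5 ± 0.28, 0 of 6 ΔdnrD, 2 of 3 wt after), Dshi_3605 (1.23 ± 0.29, 1 of 3 ΔdnrD before, floor 0.57), the transporter gene Dshi_1098 (1.19 ± 0.22) and the phosphohydrolase gene RDRS00004 (1.16 ± 0.30). At the floor the wt change of Dshi_3879 was only -0.04. Over the 10 genes, adjusted p ran from 0.000306 to 0.0443. NO reductase genes had 0 of 3 up and 2 down (0 and 3 adjusted over the list alone). The median was -1.77 or -0.66 at the bounds, 2 below background in a group (-1.11, -2.26 and -1.96 by slide), with adjusted p = 0.000168 and 0.162. The call ended on leaving out 1 array for Dshi_3605 (any but wt before 3, after 2 and 3, ΔdnrD before 2, after 3, p up to 0.0771), RDRS00004 (any but wt after 3, ΔdnrD before 2, after 3, p up to 0.148) and RDRS03978 (wt before 1 and 2, after 1 and 2, ΔdnrD before 1, after 2, p up to 0.0718). The test called 86 genes, 37 higher and 49 lower, of which 32 by at least 1 on the log2 scale and 86 the same way on all 3 slides. The count became 0 with normexp background (47 by limma at an unadjusted p under 0.05), 30 with the brightest probe, 235 on the authors' matrix values and 426 with array weights. The count was 51 over probes well above background and 7 with only the arrays compared. Without wt replicates 1 and 2 before NO it was 25 and 23. Without wt replicates 1 and 3 after NO it was 22 and 234. Without ΔdnrD replicate 1 before NO it was 39. Without ΔdnrD replicates 2 and 3 after NO it was 32 and 496. The split became 40 higher and 33 lower with quantile normalization and 216 higher and 19 lower with the authors' matrix values.

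In ΔdnrF the responses of norC (-1.66 ± 0.40, 2 of 3 ΔdnrF after, 0 of 3 ΔdnrF before), dnrE (-1.57 ± 0.30, floor -0.98) and ctrA (-1.21 ± 0.18, 0 of 6 wt) were lower than in wt. Lower too were those of the hypothetical protein genes Dshi_1086 (-1.23 ± 0.21) and Dshi_3358 (-1.21 ± 0.23, 0 of 6 wt). Higher responses were those of Dshi_0816 (1.30 ± 0.31), the integrase gene Dshi_3696 (1.38 ± 0.27, 0 of 3 ΔdnrF after) and Dshi_3879 (2.08 ± 0.28, 0 of 6 ΔdnrF, 2 of 3 wt after). Others were Dshi_1865 (1.62 ± 0.32, 0 of 6 ΔdnrF, 1 of 3 wt after) and Dshi_2466 (1.33 ± 0.29, 0 of 6 ΔdnrF). Over the 10 genes, adjusted p ran from 0.00076 to 0.0391. The difference did not pass for norB (-0.78 ± 0.33, 0 of 6 ΔdnrF, 0 of 3 wt before, adjusted p = 0.354) or nirG (-1.32 ± 0.45, 1 of 3 ΔdnrF after, 0 of 3 ΔdnrF before, 1 of 3 wt before, adjusted p = 0.185). Single arrays decided the call of Dshi_0816 (any but wt after 3, p up to 0.125), Dshi_1865 (ΔdnrF before 3, p up to 0.0552), Dshi_2466 (wt before 1, after 2, ΔdnrF before 1 and 3, after 2 and 3, p up to 0.0815), norC (any but wt after 1 and 2, ΔdnrF after 1, p up to 0.128), dnrE (ΔdnrF after 3, p up to 0.0577), Dshi_3358 (wt before 2, ΔdnrF after 3, p up to 0.0577) and Dshi_3696 (ΔdnrF before 3, p up to 0.0547). The test called 49 genes, 25 higher and 24 lower, of which 21 by at least 1 on the log2 scale and 49 the same way on all 3 slides. The count became 0 with normexp background (26 by limma at an unadjusted p under 0.05), 24 with quantile normalization, 16 with the brightest probe and 76 on the authors' matrix values. The count was 137 with array weights and 199 with the replicate block. Without wt replicates 1, 2 and 3 before NO it was 19, 12 and 24. Without wt replicates 1, 2 and 3 after NO it was 19, 23 and 88. Without ΔdnrF replicates 2 and 3 before NO it was 14 and 12. Without ΔdnrF replicates 2 and 3 after NO it was 25 and 8. The split became 22 higher and 35 lower with median scaling and 58 higher and 18 lower with the authors' matrix values. The sign turned for Dshi_2466 with the authors' matrix values and normexp background and for Dshi_3696 with normexp background.

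Before NO, cbb3 oxidase genes and single tetrapyrrole genes were lower in ΔfnrL than in wt. Lower in ΔfnrL were the OmpW family gene Dshi_1299 (-9.43 ± 0.22, 1 of 3 ΔfnrL, floor -8.24), uspA Dshi_1338 (-7.75 ± 0.21, floor -6.58), bchE (-7.72 ± 0.14) and Dshi_2621 (-7.54 ± 0.18, 1 of 3 ΔfnrL, floor -6.39). Others were Dshi_0715 (-7.45 ± 0.18), Dshi_0818 (-7.23 ± 0.15, 1 of 3 ΔfnrL, floor -5.73) and the cytochrome c gene Dshi_2672 (-7.17 ± 0.41, 1 of 3 ΔfnrL, floor -6.49). Below background there were Dshi_0814 (at least 110-fold), Dshi_2622 (at least 94-fold) and bchJ (at least 62.3-fold). The bchE and bchJ genes belong to bacteriochlorophyll synthesis. Genes of the high-affinity cbb3 oxidase, which respires oxygen at low levels, had 0 of 10 up and 9 down (0 and 9 adjusted over the list alone). The median was -2.87 (-3.04, -2.85 and -2.71 by slide), with adjusted p = 6.65e-20 and 0.00881. The largest falls were in fixO (-4.75 ± 0.14), fixP (-4.24 ± 0.12), fixN (-4.0 ± 0.11) and fixQ (-3.89 ± 0.17). The nosZ gene stood at -4.40 ± 0.52, nirS was at least 3.12-fold lower, napF higher by 1.61 ± 0.12 and the other called nap genes lower. The heme and tetrapyrrole list had 0 of 17 up and 5 down (0 and 5 adjusted over the list alone). The median was -0.08 (-0.02, -0.19 and -0.10 by slide), turning to 0.43 with the authors' matrix values, with adjusted p = 8.92e-05 and 0.0118. Lower were hemN Dshi_0659 (-6.69 ± 0.16, floor -5.80), hemN Dshi_0541 (-4.46 ± 0.18) and hemA Dshi_3190 (-1.84 ± 0.27), and hemN encodes an oxygen-independent step of heme synthesis.

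Higher in ΔfnrL and below background in wt were ctrA (at least 32.3-fold), Dshi_3974 (at least 6.84-fold), Dshi_3975 (at least 6.02-fold), virB5 Dshi_3644 (at least 7.36-fold) and virB4 Dshi_3641 (at least 5-fold). Others were cpdB (at least 8.65-fold), virB2 Dshi_3639 (at least 4.95-fold), virB3 Dshi_3640 (at least 3.69-fold) and the hybrid histidine kinase gene Dshi_1644 (at least 7.74-fold). Dshi_1470, a hypothetical protein gene measured in both, was higher by 6.61 ± 0.12, floor 5.52. CtrA is a regulator of motility in related bacteria. Over the set of 20 genes, adjusted p ran from 3.55e-22 to 9.03e-12. Plasmid replication and transfer genes had 27 of 41 up and 1 down (30 and 1 adjusted over the list alone). The median was 1.16 or 0.54 at the bounds (1.12, 1.24 and 1.0 by slide), with adjusted p = 1.16e-12 and 0.0537. The test called 1072 genes, 734 higher and 338 lower. Of these, 315 changed by at least 1 on the log2 scale, 1063 moved the same way on all 3 slides and 14 lay below background in both groups. The count became 220 with normexp background, 3183 on the authors' matrix values and 1990 against the other 2 mutants, an alternative added after the data were seen. The split became 543 higher and 410 lower with median scaling and 3020 higher and 163 lower with the authors' matrix values.

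Before NO, ΔdnrD had far higher flagellar and plasmid transfer transcripts than wt. The flagellin gene fliC (7.36 ± 0.13, 1 of 3 wt) and the hook gene flgE (6.86 ± 0.29, 2 of 3 wt, floor 5.77) were higher. Higher in ΔdnrD and below background in wt were ctrA (at least 64.8-fold), Dshi_3974 (at least 65.2-fold), Dshi_3975 (at least 49.4-fold) and the anti-sigma factor antagonist gene Dshi_0073 (at least 36.7-fold). Others were the LuxR family gene Dshi_2852 (at least 58.4-fold), virB2 Dshi_3639 (at least 36.1-fold), virB3 Dshi_3640 (at least 23.8-fold) and virB5 Dshi_3644 (at least 37-fold). Flagellar and chemotaxis genes had 31 of 33 up and 1 down (31 and 2 adjusted over the list alone). The median was 5.29 or 4.25 at the bounds (5.24, 5.37 and 4.98 by slide), with adjusted p = 1.65e-28 and 0.0347. Plasmid replication and transfer genes had 25 of 41 up and 5 down (25 and 5 adjusted over the list alone). The median was 2.16 or 1.62 at the bounds (2.38, 2.23 and 2.03 by slide), with adjusted p = 8.73e-11 and 0.137. Lower in ΔdnrD were glnK (-4.60 ± 0.69, floor -3.80), the phage tail protein gene Dshi_2465 (-3.19 ± 0.20, 1 of 3 ΔdnrD, floor -2.64), Dshi_2464 (-2.98 ± 0.20, 1 of 3 ΔdnrD, floor -1.68) and Dshi_2778 (-2.97 ± 0.23). Below background there were amtB (at least 10.5-fold), the TRAP transporter gene Dshi_1924 (at least 4.07-fold), Dshi_2466 (at least 3.38-fold), the dehydrogenase gene Dshi_0598 (at least 2.76-fold) and the transporter gene Dshi_0111 (at least 2.78-fold). The amtB and glnK genes encode the ammonium transporter and its regulator. Over these 19 genes, adjusted p ran from 2.91e-22 to 9.03e-06. All 7 nap genes were higher, with napF at 1.74 ± 0.12. The test called 1873 genes, 950 higher and 923 lower. Of these, 571 changed by at least 1 on the log2 scale, 1854 moved the same way on all 3 slides and 10 lay below background in both groups. The count became 423 with normexp background. The split became 719 higher and 1410 lower with quantile normalization, 786 higher and 1240 lower with median scaling and 1973 higher and 410 lower with the authors' matrix values.

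ΔdnrF before NO also had higher flagellar and plasmid transfer transcripts than wt. Higher in ΔdnrF and below background in wt were ctrA (at least 74.9-fold), Dshi_3974 (at least 89.7-fold), Dshi_3975 (at least 76.1-fold), virB2 Dshi_3639 (at least 68.3-fold) and virB3 Dshi_3640 (at least 48.6-fold). Others were virB4 Dshi_3641 (at least 49.4-fold), virB5 Dshi_3644 (at least 59.1-fold), Dshi_3638 (at least 45.6-fold), Dshi_2852 (at least 67-fold) and flgB (at least 25.4-fold). The flagellar and chemotaxis list had 31 of 33 up and 0 down (31 and 1 adjusted over the list alone). The median was 5.20 or 4.21 at the bounds (5.22, 5.30 and 5.13 by slide), with adjusted p = 1.77e-24 and 0.0621. Plasmid replication and transfer genes had 26 of 41 up and 4 down (26 and 4 adjusted over the list alone). The median was 2.49 or 1.30 at the bounds (2.71, 2.34 and 2.46 by slide), with adjusted p = 6.58e-09 and 0.24. Lower in ΔdnrF were glnK (-4.81 ± 0.69, floor -4.07) and the periplasmic binding protein gene Dshi_0561 (-3.68 ± 0.60, 1 of 3 ΔdnrF). Below background there were amtB (at least 12.7-fold), Dshi_1924 (at least 4.9-fold), Dshi_2466 (at least 4.07-fold) and Dshi_2465 (at least 7.52-fold). Others were Dshi_3281 (at least 7.94-fold), Dshi_1778 (at least 4.73-fold) and Dshi_2464 (at least 3.85-fold). Over these 19 genes, adjusted p ran from 1.70e-22 to 2.16e-05. The test called 2023 genes, 1212 higher and 811 lower. Of these, 622 changed by at least 1 on the log2 scale, 2019 moved the same way on all 3 slides and 11 lay below background in both groups. The count became 564 with normexp background. The split became 835 higher and 1322 lower with quantile normalization and 893 higher and 1196 lower with median scaling.

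**Figure D3:**
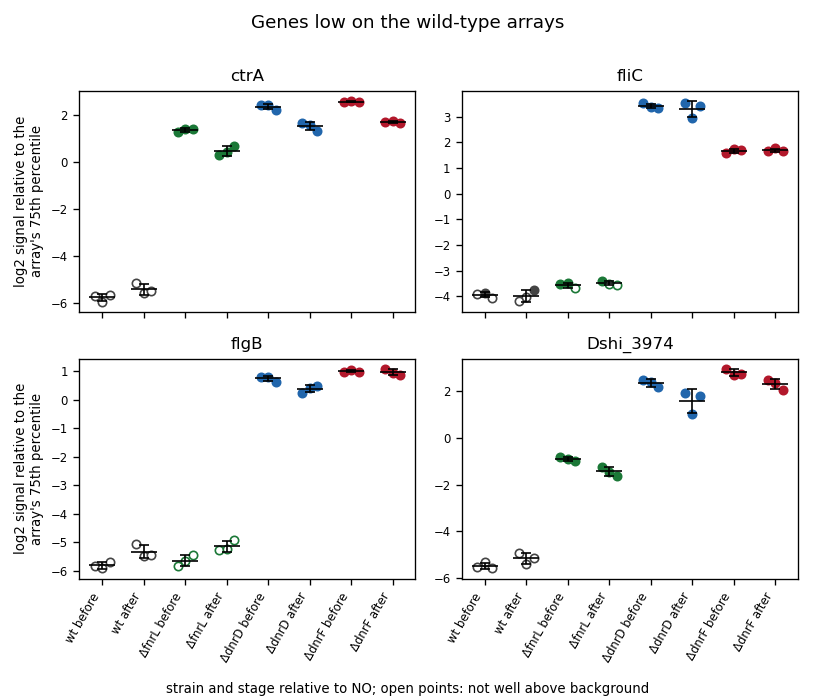
Signal of ctrA, fliC, flgB and the plasmid transfer gene Dshi_3974 as log2 relative to the array's 75th percentile, with 1 point per array, open where not well above background, and the mean ± SD of each group of 3 arrays. Before NO, ctrA stood at -5.78 ± 0.15 in wt, 1.34 ± 0.08 in ΔfnrL, 2.34 ± 0.12 in ΔdnrD and 2.55 ± 0.02 in ΔdnrF, and fliC at -3.94 ± 0.10, -3.57 ± 0.10, 3.42 ± 0.09 and 1.68 ± 0.07.

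After NO, ΔfnrL stood above wt in norC (2.49 ± 0.28), nirH (2.95 ± 0.37), dnrE (2.29 ± 0.21), norB (1.22 ± 0.24) and nirG (1.06 ± 0.32). It stood below wt in nosZ (-3.58 ± 0.52), and nirS did not pass (0.48 ± 0.30, adjusted p = 0.25). The largest lower values were those of Dshi_1299 (at least 287-fold), Dshi_2622 (at least 70.8-fold), bchJ (at least 45-fold), Dshi_2672 (at least 79.3-fold) and Dshi_0818 (-6.98 ± 0.15, 1 of 3 ΔfnrL, floor -5.53). The largest higher values were those of Dshi_1470 (6.08 ± 0.12, floor 5.11), ctrA (at least 13.9-fold), virB4 Dshi_3641 (at least 4.89-fold), cpdB (at least 6.34-fold) and Dshi_3975 (at least 3.92-fold). Over these 10 genes, adjusted p ran from 1.12e-21 to 8.23e-12. Without 1 array the call ended for nirG (wt 1 and 2, ΔfnrL 3, p up to 0.0858). The test called 1149 genes, 795 higher and 354 lower. Of these, 333 changed by at least 1 on the log2 scale, 1123 moved the same way on all 3 slides and 26 lay below background in both groups. The count became 222 with normexp background, 3260 on the authors' matrix values and 1914 against the other 2 mutants. The split became 684 higher and 476 lower with quantile normalization, 565 higher and 508 lower with median scaling and 3138 higher and 122 lower with the authors' matrix values.

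ΔdnrD after NO stood below wt in norC (at least 2.98-fold), nirG (at least 1.73-fold), norB (no fold given), nirH (-1.86 ± 0.37, 2 of 3 ΔdnrD) and dnrE (-1.74 ± 0.21, floor -1.11). Its nirS value was -0.75 ± 0.30 (adjusted p = 0.0444). The largest higher values were those of fliC (7.29 ± 0.13, 1 of 3 wt, floor 6.64), ctrA (at least 28.7-fold), Dshi_3974 (at least 30.5-fold), Dshi_2852 (6.59 ± 0.12, 1 of 3 wt, floor 5.52) and Dshi_3975 (at least 25.4-fold). The largest lower, beside dnrD itself, were those of amtB (at least 12.7-fold), glnK (-4.69 ± 0.69, floor -3.87), Dshi_1924 (at least 3.87-fold) and Dshi_2778 (-3.37 ± 0.23). Over these 9 genes, adjusted p ran from 4.05e-21 to 6.72e-06. The call ended on leaving out 1 array for nirS (any but ΔdnrD 1, p up to 0.159). The test called 1755 genes, 840 higher and 915 lower. Of these, 575 changed by at least 1 on the log2 scale, 1656 moved the same way on all 3 slides and 21 lay below background in both groups. The count became 371 with normexp background. The split became 725 higher and 1392 lower with quantile normalization, 717 higher and 1346 lower with median scaling and 2318 higher and 263 lower with the authors' matrix values. The sign turned for norB with the authors' matrix values.

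ΔdnrF after NO stood below wt in norC (-2.15 ± 0.28, 2 of 3 ΔdnrF, floor -1.17), norB (no fold given), nirG (-1.52 ± 0.32, 1 of 3 ΔdnrF, floor -0.38), nirH (-1.48 ± 0.37, 1 of 3 ΔdnrF, floor -0.89), dnrE (-1.14 ± 0.21) and nirS (-0.96 ± 0.30). The largest higher values were those of Dshi_3974 (at least 50.3-fold), Dshi_3975 (at least 44.5-fold), ctrA (at least 32.8-fold), virB2 Dshi_3639 (at least 39.3-fold) and virB4 Dshi_3641 (at least 28.1-fold). The largest lower, beside dnrF itself, were those of amtB (at least 9.59-fold), the nuclease family gene Dshi_3281 (at least 5.57-fold), glnK (-4.51 ± 0.69, floor -3.46) and Dshi_0561 (-3.78 ± 0.60, 1 of 3 ΔdnrF, floor -3.09). Over these 9 genes, adjusted p ran from 3.11e-21 to 1.72e-05. Single arrays decided the call of nirS (wt 1, ΔdnrF 3, p up to 0.069). The test called 1912 genes, 1272 higher and 640 lower. Of these, 555 changed by at least 1 on the log2 scale, 1889 moved the same way on all 3 slides and 47 lay below background in both groups. The count became 424 with normexp background. The split became 792 higher and 1202 lower with quantile normalization and 801 higher and 1073 lower with median scaling.

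The 3 mutants were compared with the same 3 wt arrays before NO, so part of their overlap can come from those arrays, which were too few to split. In all 3, 433 genes were called the same way, 308 higher and 125 lower. Independent lists give 61 and 18.3. ΔfnrL and ΔdnrD shared 624 calls of the same direction (423 higher, 201 lower) and 73 of opposite direction. Independent lists give 187 higher and 83.8 lower in both. ΔfnrL and ΔdnrF shared 546 calls of the same direction (400 higher, 146 lower) and 127 of opposite direction. Independent lists give 239 higher and 73.7 lower in both. ΔdnrD and ΔdnrF shared 1324 calls of the same direction (715 higher, 609 lower) and 38 of opposite direction. Independent lists give 309 higher and 201 lower in both.

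The NO responses of the 4 strains share no arrays, and their Pearson r was taken across genes, which are not independent replicates. For wt and ΔfnrL it was 0.671 (rho 0.721, r of 0.481, 0.59 and 0.69 by slide), with 56 genes called higher and 148 lower in both. For wt and ΔdnrD it was 0.317 (rho 0.321, r of 0.291, 0.0476 and 0.526 by slide), with 23 genes called higher and 111 lower in both. For wt and ΔdnrF it was 0.585 (rho 0.587, r of 0.564, 0.471 and 0.541 by slide), with 61 genes called higher and 128 lower in both. For ΔfnrL and ΔdnrD it was 0.465 (rho 0.563, r of 0.47, 0.256 and 0.455 by slide), with 85 genes called higher and 178 lower in both. For ΔfnrL and ΔdnrF it was 0.563 (rho 0.639, r of 0.513, 0.468 and 0.5 by slide), with 109 genes called higher and 157 lower in both. For ΔdnrD and ΔdnrF it was 0.693 (rho 0.66, r of 0.686, 0.314 and 0.671 by slide), with 166 genes called higher and 207 lower in both. Genes called the same way in all 4 strains numbered 17 higher and 76 lower, where independent lists give 0.0544 and 0.23. Of these 93, 82 were well above background on all 24 arrays, and 1, Dshi_2686, was so on none of the 6 ΔfnrL arrays.

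Of the 455 list tests 131 passed, 16 of them also with an estimated correlation, that of Crp/Fnr regulators in the response of ΔfnrL only with fnrL counted. Lists called but not described above, with the number of comparisons that called them and their medians there, were denitrification (7, -0.99 to 0.51), nos (4, -1.45 to 0.64), ATP synthase (3, -0.50 to -0.36), NADH dehydrogenase (1, -0.22), TCA cycle (2, -0.28 to -0.24), other terminal oxidases (1, 0.20), PHB metabolism (2, -0.39 to -0.28), photosynthesis (6, -1.23 to -0.48), universal stress proteins (3, 0.01 to 0.25). Others were transposases (4, 0.07 to 0.27), DNA repair (2, 0.10 to 0.11), NO detoxification (3, -1.31 to 0.52), plasmid pDSHI01 (6, 0.06 to 0.29), plasmid pDSHI02 (5, -0.43 to 0.09), plasmid pDSHI03 (10, -0.24 to 1.08), plasmid pDSHI04 (7, -0.18 to 0.80), plasmid pDSHI05 (3, 0.13 to 0.28). With an estimated correlation only calls of pDSHI02, pDSHI03 and pDSHI04 among these held (1, 3 and 2), and over all 115 list calls lost there adjusted p ran from 0.0503 to 0.999. The phaC to phaG members of the PHB list are annotated as cation/proton antiporter subunits. Further, nirS stands in the NO detoxification list as an annotated hydroxylamine reductase, and the list of other terminal oxidases holds carbon monoxide dehydrogenase genes. Lists that no comparison called, with their lowest adjusted p, were chaperones and proteases (0.113), cobalamin synthesis (0.0761), copper and electron carriers (0.378), cytochrome c maturation (0.0805), gene transfer agent and phage (0.108), iron uptake (0.135), iron-sulfur cluster assembly (0.326), oxidative stress (0.0708), quorum sensing (0.294).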

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

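The tests of exchanged arrays, of a wt culture that stands apart, of genes above and below background, of 30 further minutes in the flask and of a lower starting level were chosen only after the results were seen. The NO response of ΔfnrL differed from that of wt in 35 genes, fnrL itself among them, that of ΔdnrD in 86 and that of ΔdnrF in 49, by limma's test of the difference itself. The values here are fitted log2 differences of the responses, mutant minus wt. Those of genes below background in a group carry the limits given with them in the report. In ΔfnrL, higher responses were those of Dshi_1454 (6.27), nirH (4.64), nirS (4.18), Dshi_3192 (4.16), Dshi_0814 (4.03), dnrF (1.65) and dnrE (2.22). Others were nirJ (1.60), nirG (2.24), norC (2.88), norB (1.99), nosR Dshi_3193 (1.35) and nosR RDRS03175 (1.11). Lower ones were those of ctrA (-1.23), Dshi_3983 (-1.05), Dshi_3980 (-1.0), virB3 Dshi_3640 (-0.94) and virB8 Dshi_3645 (-0.91). The value of fnrL itself (1.09) is no response of ΔfnrL, which lacks the gene and had it below background on all 6 arrays. The gene lists called in ΔfnrL had these medians, each followed by that with responses at their bounds where this differs, Crp/Fnr regulators (0.20), denitrification (0.50 or 0.058), DNA repair (0.096), heme and tetrapyrrole synthesis (0.067, turning to -0.17 with the authors' matrix values), nir (1.27 or -0.046) and NO detoxification (0.48 or 0.069). Others were nor (1.99 or 1.06), nos (0.64 or 0.20), plasmid pDSHI03 (-0.18 or -0.14, turning to 0.40 with normexp background and 0.22 with the authors' matrix values), plasmid replication and transfer (-0.16 or -0.14, turning to 0.33 with normexp background and 0.13 with the authors' matrix values) and ribosomal proteins (-0.13). With an estimated correlation the calls of Crp/Fnr regulators, heme and tetrapyrrole synthesis, nir and nor held, the first only with fnrL counted (adjusted p = 0.066 without it, median 0.10), and for the others adjusted p ran from 0.0677 to 0.909. Leaving out 1 array ended DNA repair (wt before 1, after 2, ΔfnrL before 1, after 3, p up to 0.14) and ribosomal proteins (wt before 1, after 2, ΔfnrL after 3, p up to 0.67). In ΔdnrD, higher responses were those of cytC (1.57), Dshi_3879 (1.5), Dshi_3605 (1.23), Dshi_1098 (1.19) and RDRS00004 (1.16), and lower ones those of norC (-3.02), nirG (-2.68), dnrE (-2.37), norB (-1.77) and RDRS03978 (-1.39). The lists called in ΔdnrD were ATP synthase (-0.43), denitrification (-0.43 or -0.35), DNA repair (0.11 or 0.13), flagella and chemotaxis (-0.67 or -0.36), nir (-0.58) and nor (-1.77 or -0.66). Others were plasmid pDSHI03 (-0.24 or -0.22), plasmid replication and transfer (-0.26 or -0.22), ribosomal proteins (-0.37), TCA cycle (-0.28) and transposases (0.073 or 0.098). None of these calls held with an estimated correlation, where adjusted p ran from 0.162 to 0.766. Single arrays decided DNA repair (any but wt before 2, after 1 and 3, ΔdnrD before 2, after 1, p up to 0.131), nir (wt before 3, ΔdnrD before 1, after 3, p up to 0.135), plasmid pDSHI03 (ΔdnrD after 3, p up to 0.0588), plasmid replication and transfer (ΔdnrD after 3, p up to 0.0566) and transposases (wt before 3, after 1 and 2, ΔdnrD before 1, after 2 and 3, p up to 0.146). In ΔdnrF, higher responses were those of Dshi_3879 (2.08), Dshi_1865 (1.62), Dshi_3696 (1.38), Dshi_2466 (1.33) and Dshi_0816 (1.30), and lower ones those of norC (-1.66), dnrE (-1.57), Dshi_1086 (-1.23), Dshi_3358 (-1.21) and ctrA (-1.21). The lists called in ΔdnrF were denitrification (-0.14), flagella and chemotaxis (-0.60 or -0.25), nor (-0.78 or -0.53), plasmid pDSHI03 (-0.066 or -0.057), plasmid replication and transfer (-0.19 or -0.16) and ribosomal proteins (-0.10). None of these calls held with an estimated correlation, where adjusted p ran from 0.339 to 0.883. Without 1 array there ended denitrification (wt before 3, p up to 0.0612), nor (wt after 3, p up to 0.0578) and ribosomal proteins (wt before 1, after 2, ΔdnrF before 2, after 3, p up to 0.623).

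In each of the 13 comparisons, 1 of the 10 splits of the 6 values compared, the real one, gave as many genes as the real split. The values were arrays or, for the responses, same-number differences. Fitted on those 6 values alone, the real counts were 92, 603, 43 and 1194 after NO in wt, ΔfnrL, ΔdnrD and ΔdnrF. For ΔfnrL, ΔdnrD and ΔdnrF they were 1220, 1802 and 2285 against wt before NO, 863, 1247 and 1829 after it and 101, 8 and 352 for the differences of responses. The highest count of any other split was 0 in each comparison by limma, with up to 426 genes at an unadjusted p under 0.05. Of the 10 splits 4 parted all 3 same-number pairs, the real one among them, and 6 parted 1. With 10 splits no share under 0.05 can be reached.

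On the 6 wt arrays, 23 genes that were well above background on all 18 mutant arrays were not, among them ctrA and plasmid transfer genes of pDSHI01 and pDSHI03, while flagellar genes had medians of 5.29 in ΔdnrD and 5.20 in ΔdnrF against wt before NO. Exchanged arrays are argued against. On 0 of the 18 mutant arrays was its own deleted gene well above background, and 0 of all 24 lacked one deleted elsewhere. Place on the slide goes with strain and stays open. In 4 areas of the array, probes of ctrA, flagellar and plasmid transfer genes shifted between ΔdnrD and wt by medians of 3.59 to 5.43. Other probes, once scaled, shifted by 0.0252 at most. A wt culture that stood apart stays open, because each mutant was set against the same wt cultures. In the flagellar part ΔfnrL differed from wt by a median of 0.16 or 0 at the bounds (-0.01, 0.25 and 0.23 by slide). There 19 of 33 genes were below background in a group. For plasmid transfer the lowest of the 3 medians was 1.16 or 0.54 at the bounds. An effect shared by the 3 deletions could give this too. Effects of the regulators on motility and plasmid transfer genes stay open and were not tested.

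Most changes after NO were below 1 on the log2 scale, and 93 genes were called in the same direction in all 4 strains, where independent lists give 0.284. A difference in signal over background before and after NO stays open as a cause. The normexp counts in wt, ΔfnrL, ΔdnrD and ΔdnrF cannot tell, as all took in the spread of ΔfnrL. Across genes, only a trend of the change with the level in the other strains was tested. Its Spearman correlations were -0.0306, -0.0261, 0.0300 and -0.0695, under 0.1 in size on each slide but slide 2 in ΔdnrF (-0.167). For genes well above background on all 6 arrays of a strain they were 0.0222, 0.0207, 0.0435 and 0.0213. Under 0.1 on each slide, these argue against a trend. These genes made up 292, 422, 690 and 553 of the calls. For those below it on all 6, 19, 28, 7 and 35 of the calls, the difference may be the cause. Their median change was 0.32, 0.35, -0.079 and 0.40, over 0.1 on each slide but in ΔdnrD (0.049, -0.40 and 0.085), which stays open. Another 30 min in the closed flask or the row on the slide could account for the 93 shared genes and cannot be told apart from NO, because no flask without NO was sampled and each stage had its own row. An effect of NO that needs none of the 3 regulators stays open and was not tested.

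The 27 genes other than fnrL with a larger NO response in ΔfnrL than in wt, norC, norB, nirS and nirH among them, had a median difference of responses of 2.24, or 1.76 with responses at their bounds, as 10 were below background in a group, 9 of them in ΔfnrL before NO. Scaling between arrays is argued against as the cause, since the median was 2.22 with quantile normalization. Before NO, 21 of the 27 were called lower in ΔfnrL than in wt, by a median of -1.95, or -1.33 at the bounds, over the 27. After NO 12 were called higher and 10 lower, with a median of 0.48 (-0.06, 0.74 and 0.89 by slide). For the 12, a level above wt argues against a lower start as the whole cause. For the rest, not called higher, it stays open. A role of FnrL in limiting the response may be a biological explanation and was not tested.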

How the results depend on the processing

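The text gives 292 fitted differences of 126 genes, and 275 of them passed. Of these, the direction and the call held for 275 with no filter, 275 with the slide as a block, 274 with median scaling and 269 with array weights. They held for 262 with quantile normalization, 242 with only the arrays compared, 247 of 263 over probes well above background, 237 with any 1 array left out, 219 with the brightest probe, 242 on the authors' matrix values and 131 with normexp background. At an absolute log2 difference of 1 or more 239 stayed called. The replicate block ended the call of 1 of them and called 4 of the others, nirS in the response of ΔdnrD against wt (adjusted p = 0.0486), nirS in wt after NO (adjusted p = 0.00338), nirH in the response of ΔdnrD against wt (adjusted p = 0.0185) and nirH in ΔdnrF after NO (adjusted p = 0.0251). Over all settings adjusted p of these 4 ran from 0.00181 to 1. Signal over background limits the genes below it, whose folds are bounds and whose differences of responses are only fitted, and with normexp the median SD between replicates was 0.797 in ΔfnrL after NO against 0.15. Where no value or construction shows the cause of a move below, the cause was not tested.

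Counts for all strains are in the order wt, ΔfnrL, ΔdnrD and ΔdnrF, without wt where it is the reference. With normexp background they were 0, 79, 1 and 3 for the change after NO and 220, 423 and 564 before NO against wt. They were 222, 371 and 424 after NO against wt and 14, 0 and 0 for the difference of responses. Counts of 0 held 114, 47 and 26 by limma at an unadjusted p under 0.05. On the authors' matrix values, whose scale differs between groups, they were 234, 2246 and 1080 for the change after NO in wt, ΔfnrL and ΔdnrF and 3183 before NO against wt in ΔfnrL. They were 3260 after NO against wt in ΔfnrL and 1545, 235 and 76 for the difference of responses. With array weights they were 876, 1410 and 1390 for the change after NO in ΔfnrL, ΔdnrD and ΔdnrF and 426 and 137 for the difference of responses in ΔdnrD and ΔdnrF. Fits of only the arrays compared have their own spread (median SD by group 0.098 to 0.21) and fewer degrees of freedom. They gave 92, 43 and 1194 for the change after NO in wt, ΔdnrD and ΔdnrF and 7 for the difference of responses in ΔdnrD. The threshold of 1 on the log2 scale, which can only lower a count, gave 19, 57, 37 and 32 for the change after NO and 315, 571 and 622 before NO against wt. They were 333, 575 and 555 after NO against wt and 32 and 21 for the difference of responses in ΔdnrD and ΔdnrF. The brightest probe gave 21, 30 and 16 for the difference of responses, probes well above background 51 for the difference of responses in ΔdnrD, and quantile normalization 24 for the difference of responses in ΔdnrF. The other 2 mutants as the reference, an alternative added after the data were seen, gave 1990 for ΔfnrL before NO and 1914 after it. Of 120 called values of single genes against wt 97 kept direction and call, 9 lost the call and 14 changed sign, as that reference asks another question. Leaving out 1 array, with the pair left assumed to vary like the other groups, gave 88 to 314, 282 to 432, 458 to 1080 and 410 to 548 genes for the change after NO. It gave 821 to 1024, 1615 to 1787 and 1772 to 1894 before NO against wt, 958 to 1109, 1567 to 1817 and 1684 to 1804 after NO and 27 to 46, 22 to 496 and 8 to 88 for the differences of responses. No other count of genes moved by over 1.5 times under these settings, median scaling, no filter or the slide block.

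Of the 131 list calls 114 held with quantile normalization, 94 with any 1 array left out and 124 with the replicate block. Without the deleted genes in the lists, an alternative added after the data were seen, 131 list tests passed, 15 with an estimated correlation. The replicate block ended nor in ΔdnrD against wt after NO (adjusted p = 0.0549), nor in ΔdnrF after NO (adjusted p = 0.0937), plasmid pDSHI02 in ΔdnrF after NO (adjusted p = 0.0761), plasmid pDSHI04 in ΔdnrF after NO (adjusted p = 0.0728), universal stress proteins in ΔdnrF after NO (adjusted p = 0.0728), heme and tetrapyrrole synthesis in ΔfnrL after NO (adjusted p = 0.172) and plasmid pDSHI04 in ΔfnrL after NO (adjusted p = 0.115). The slide block ended nor in ΔdnrF after NO (adjusted p = 0.0708) and universal stress proteins in ΔdnrF after NO (adjusted p = 0.0581). The calls shared by mutants before NO fell at the threshold of 1 to 110 for all 3 and to 167, 119 and 426 for ΔfnrL with ΔdnrD, ΔfnrL with ΔdnrF and ΔdnrD with ΔdnrF, with fewer genes entering.

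With the replicate block the counts were 947, 1051, 1303 and 1256 for the change after NO and 55, 383 and 199 for the difference of responses. The slide block gave 532, 639, 906 and 866 and 40, 103 and 60. In ΔdnrD replicate 2 did not pair (r = 0.0225). Beside the values given, the replicate block changed no other passing call of a named gene than virB3 Dshi_3640 in the response of ΔfnrL against wt (adjusted p = 0.0558), and moved no other count by over 1.5 times.

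Values that passed and changed sign were these, given as log2 differences. On the authors' matrix values the sign turned for Dshi_0047 (0.41), Dshi_3654 (0.047) and Dshi_4067 (0.50) in ΔfnrL after NO, Dshi_2466 (-0.13) in the response of ΔdnrF against wt, norB (0.0080) in ΔdnrD against wt after NO and virB3 Dshi_3640 (0.064), Dshi_3980 (0.25) and Dshi_3983 (0.47) in the response of ΔfnrL against wt. With normexp background it turned for typA (0.21), Dshi_0047 (0.65), guaA (0.11), Dshi_3461 (0.033), Dshi_3654 (0.33) and Dshi_4067 (0.60) in ΔfnrL after NO, Dshi_2466 (-0.0025) and Dshi_3696 (-0.082) in the response of ΔdnrF against wt, Dshi_2874 (0.080) and Dshi_2991 (0.092) in ΔdnrD after NO and virB3 Dshi_3640 (0.033), Dshi_3980 (0.28) and Dshi_3983 (0.31) in the response of ΔfnrL against wt. With the brightest probe it turned for nirJ (-0.20) and Dshi_3980 (0.11) in the response of ΔfnrL against wt and repB (0.12) in ΔdnrD after NO.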

Other observations

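A set of 12 genes was well above background on all 18 arrays of the other strains and on none of the 6 ΔfnrL arrays. They are given, beside fnrL and bchJ, with mean log2 levels relative to the array's 75th percentile in the other strains and in ΔfnrL. With an annotated product they were dmsA, a molybdopterin oxidoreductase (0.16 and -4.79), the cytochrome c peroxidase gene ccpA (1.41 and -5.23), the UspA domain protein gene Dshi_2686 (0.97 and -5.43), the DUF395 protein gene Dshi_1097 (-0.04 and -4.89), the peptidase gene Dshi_0942 (-1.91 and -5.17), the abortive infection protein gene Dshi_0943 (-1.71 and -5.36) and dnaQ (0.16 and -5.19). Those encoding hypothetical proteins were Dshi_0819 (0.90 and -5.32), Dshi_2622 (2.66 and -4.65) and Dshi_3558 (-1.87 and -5.41). A level on an array without signal above background is only a bound. In ΔdnrD the same held for 1 gene, dnrD itself, and in ΔdnrF for 2, dnrF and Dshi_3281.

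Genes called in the same direction after NO in all 4 strains, picked after their values were seen, included rnk, annotated as a GreA/GreB family elongation factor. It rose by 0.44 ± 0.13, 0.52 ± 0.13, 0.51 ± 0.13 and 0.56 ± 0.13 in wt, ΔfnrL, ΔdnrD and ΔdnrF. In the same order, guaA, for GMP synthesis, fell (-0.50 ± 0.11, -0.44 ± 0.11, -0.31 ± 0.11 and -0.46 ± 0.11), turning to 0.11 in ΔfnrL with normexp background. The GTPase gene typA fell too (-0.77 ± 0.14, -1.15 ± 0.14, -0.96 ± 0.14 and -0.82 ± 0.14), turning to 0.21 there, as did the chaperone gene secB of protein export (-0.75 ± 0.13, -0.74 ± 0.13, -0.64 ± 0.13 and -0.64 ± 0.13). Leaving out 1 array ended the call of rnk (any but before 2, after 3, p up to 0.153) and guaA (before 1, p up to 0.0503) in wt, rnk (after 2, p up to 0.0609) in ΔfnrL and rnk (after 2, p up to 0.069) and guaA (any but before 3, p up to 0.139) in ΔdnrD.

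Cultures of 1 strain differed in places. The ammonium transporter gene amtB stood at 1.0, -1.89 and 1.73 in wt replicates 1, 2 and 3 before NO and at 1.24, -1.5 and 1.92 after it. It was below background on all 18 mutant arrays (-5.31 to -4.24).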
